A study of Mus musculus with 6 samples.

How the data were processed

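RNA was sequenced from the striatum of 6-week-old mice of the outbred ICR strain, the offspring (F1) of sires treated with methylphenidate or saline. Per the labels' protocols, the sires were 6 weeks old, received 15 mg/kg methylphenidate or 10 mL/kg saline subcutaneously for 21 days, and were mated with untreated females. Methylphenidate blocks the dopamine and noradrenaline transporters and is used against attention deficit hyperactivity disorder (ADHD). The labels give 3 offspring per group, 2 females and 1 male in each. The number of sires and litters is not given in the sources used here, so p-values measure only the spread between these samples, and animals of a group may be related.

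Per the submitters' processing notes, the reads were processed with bcl2fastq 2.20.0, Trimmomatic (version not given), HISAT2 2.1.0 and StringTie 2.1.3b, with the mouse build mm10. Order, settings, strandedness and the treatment of reads that match several places are not given in the sources used here. The authors' deposited table holds 45777 RefSeq genes with whole-number read counts, which are not normalized. Whether reads were counted whole or estimated and rounded is not given in the sources used here. A further 12 columns hold FPKM and TPM values, as the authors' deposited table names them. They name a group and not a labelled animal, and 1 measure per group was kept. Tests on these columns, listed beforehand, were tried and then left out for that reason, after their results had been seen, and nothing printed here rests on them. Gene identifiers are Entrez Gene IDs, and 45679 of 45777 matched a RefSeq gene table of GRCm38.p6, the assembly that mm10 names, from which coordinates were taken.

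The columns of the table name the group and an animal number. As a set, the numbers of each group differ from those of its titles in the labels. A number found in both does not show that column and title are the same animal. Each column was therefore tied to its group and not to a particular labelled animal. The libraries are called by group and column number (3, 4 and 5 in the saline-sired group, and 2, 4 and 6 in the methylphenidate-sired group). Total counts lay between 31360042 and 38844724 per library. Library pairs correlated with Pearson r between 0.977 and 0.985 across genes, which are not independent replicates. A chi-square statistic per gene between 8.50 and 35.3 showed every pair of libraries to differ by more than sampling noise, so no library was counted as a repeat of another.

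Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) after TMM scaling. Genes were kept by filterByExpr over the groups, which left 17874 genes, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The design fixed before the data were examined had offspring sex as a covariate. It was not fitted, because no label ties a column to a sex and no library was given a sex from its expression values. A fit with no sex covariate, also listed beforehand, took its place. Log2 fold changes are methylphenidate-sired minus saline-sired. SE values were derived from the fold change and the F statistic, and CPM values use TMM-scaled library sizes. Over 37 lists fixed beforehand, gene sets were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01, where at least 3 members passed the filter (36 lists). The test was repeated with an estimated correlation, and fry was run beside it. A list score is the mean log2 CPM of its members, centred over the libraries.

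The text names genes by a rule fixed at the same time. It takes up to 12 genes per direction past the test, with an average log2 CPM of at least 1 and no overlap between the groups, leaving out predicted genes and ribosomal or mitochondrial pseudogenes. Free places go to the genes of lowest unadjusted p under the same limits. It adds members of each list past the test or otherwise the 2 of lowest p, and 13 genes of dopamine signalling, medium spiny neurons and activity. The 4 genes past the test fell outside this rule and were named after their values were seen.

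The genes past the test and the 24 ranked genes were compared by blastn 2.17.0 (expectation limit 1e-20) with the transcripts of GENCODE vM21, and near-identical copies were defined by at least 95% identity over at least 200 nucleotides. On simulated counts with 200 changed genes, made for this comparison over 17874 genes, edgeR recovered 29.9% of genes changed by 0.5 on the log2 scale, 68.7% at 1 and 80.3% at 2, with 10 calls among unchanged genes. DESeq2 recovered 47.8%, 79.1% and 83.3%, with 43 such calls. In simulated sets of 20 genes, camera at 0.01 called a set shifted by 0.3 and none of 100 unshifted sets, and with an estimated correlation it called neither (adjusted p = 0.414 for the shifted set). The genes were simulated independently of one another. Over the lists tested here, the estimated correlation ran from -0.02 (neurotrophin signalling) to 0.95 (blood markers), with 0.79 for cortical excitatory neuron markers. The simulation therefore does not show how often camera at 0.01 calls unshifted lists of correlated genes.

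Alternatives were other scalings (DESeq2 size factors, total count, upper quartile), DESeq2 1.42.0, limma-voom, other filters, robust estimation, other thresholds and leaving out each library. Added after seeing the data were Y-linked, cortical and choroid plexus marker levels as covariates, a fit without saline-sired libraries 3 and 4, and the immediate early genes that stand in no other list. The planned tests between female and male offspring were left out for the reason given above for the sex covariate.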

Results

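Striatal RNA was counted in 6 libraries from 6-week-old ICR mice, 3 from offspring of saline-treated sires and 3 from offspring of methylphenidate-treated sires. Total counts were 38844724, 31711517 and 31360042 in saline-sired libraries 3, 4 and 5, and 32984464, 32650664 and 33799383 in methylphenidate-sired libraries 2, 4 and 6. Levels are given as CPM, counts scaled to library size. Transcripts of Y-linked genes reached 181 CPM in saline-sired library 4 and 172 in methylphenidate-sired library 4, against at most 0.212 in the others. Xist, the X-inactivation transcript, was at 0.662 and 0.0919 CPM in the same libraries and at 809 or more elsewhere. The labels list 1 male per group. The libraries did not separate by group on the first principal component (28.3% of the variance), where saline-sired libraries 3 and 4 stood apart from the other 4.

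The comparison of the groups asked how striatal expression in offspring differed with the sire's treatment. Of 17874 genes tested, 4 were lower in the methylphenidate-sired group and 0 were higher at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), and all 4 are annotated pseudogenes. Rpl30-ps9 (Gene ID 622202, chromosome X, 105278583 to 105279053) fell by 5.42 on the log2 scale (SE 0.34, n = 3 per group, edgeR adjusted p = 0.00287), from 179, 143 and 100 counts to 4, 3 and 2. Rpl30-ps10 (Gene ID 100504405, chromosome X, 71803615 to 71804080) fell by 4.68 (SE 0.45, edgeR adjusted p = 0.0266). Gm12191 (Gene ID 666899, chromosome 11, 49678620 to 49679143, in an intron of Cnot6) fell by 2.52 (SE 0.18, edgeR adjusted p = 0.00356), from 12.7 ± 1.83 to 2.22 ± 0.363 CPM (SD, n = 3). Gm5182 (Gene ID 382567, chromosome 12, 10152139 to 10160206) fell by 2.35 (SE 0.25, edgeR adjusted p = 0.0452), from 22.5 ± 7.83 to 4.40 ± 0.702 CPM. Coordinates are in mm10.

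These 4 counts are uncertain, because each pseudogene is a near-identical copy of an expressed gene. Gm12191, Rpl30-ps9 and Rpl30-ps10 matched the transcript of Rpl30, a protein of the large ribosomal subunit, at 99.7%, 99.4% and 99.1% identity over their whole length. Gm5182 matched Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, at 99.2% over 6092 nucleotides. The parent genes had fold changes of the opposite sign that did not pass the test. Rpl30 was at 63.0 ± 7.96 CPM in the saline-sired and 75.5 ± 2.79 in the methylphenidate-sired group (log2 fold change 0.26, SE 0.09, edgeR adjusted p = 0.485). Acaca was at 56.1 ± 8.0 CPM and 88.3 ± 3.74 (0.65, SE 0.10, edgeR adjusted p = 0.340). DESeq2 called 183 genes, 145 higher and 38 lower, of which 2 were among the 4. It gave no adjusted p to 14122 genes, Rpl30-ps9 and Rpl30-ps10 among them. Its log2 fold changes for these 2 were -5.475 and -4.712 (DESeq2 unadjusted p = 1.24e-20 and 1.23e-17). limma-voom called 4 genes, 2 of them among these 4 and 1 protein-coding, and it did not call Rpl30-ps10 (limma-voom adjusted p = 0.0761) or Gm5182 (limma-voom adjusted p = 0.170). Rpl30-ps9 passed the edgeR test without each library in turn (highest adjusted p = 0.0379), and Gm12191 did except without methylphenidate-sired library 6 (edgeR adjusted p = 0.0735). Rpl30-ps10 passed only without methylphenidate-sired library 4 (edgeR adjusted p = 0.0352), against 0.0564 to 0.355 without each of the others. Gm5182 passed only without saline-sired library 3 or 4 (edgeR adjusted p = 0.0261 and 0.0334), against 0.0619 to 0.381 without each of the others. Without saline-sired libraries 3 and 4, which leaves 1 saline-sired library against 3, 0 genes passed the edgeR test, with 958 at an unadjusted p under 0.05. A comparison with a single library on 1 side does not show that the calls depend on the libraries left out.

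**Figure D1:**
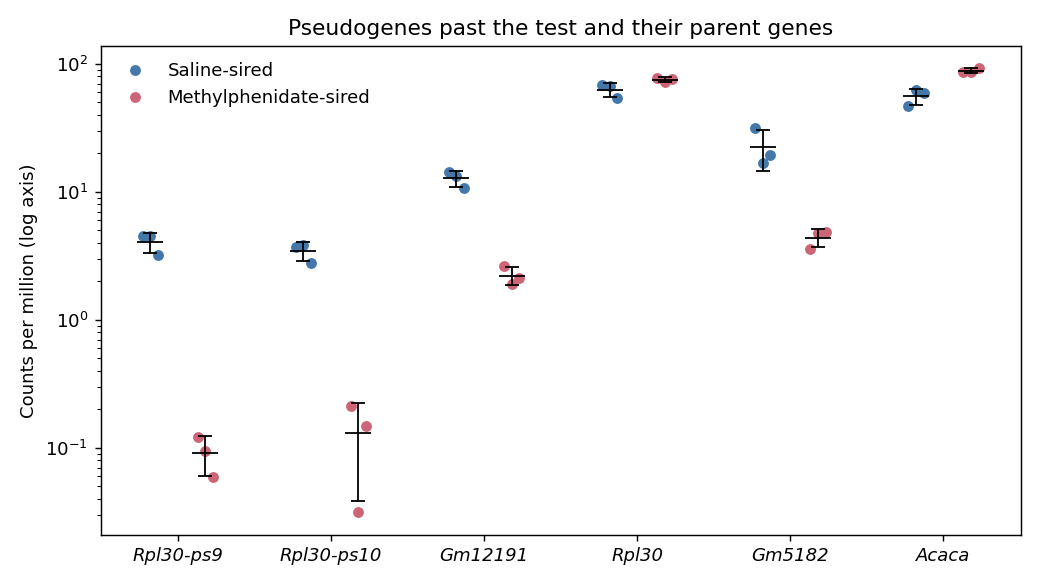
CPM (log axis) of the 4 pseudogenes past the test and of Rpl30 and Acaca, with 1 point per library and bars for the mean ± SD of 3 libraries per group. The pseudogenes are lower in all 3 methylphenidate-sired libraries, while Acaca averages 56.1 in the saline-sired and 88.3 in the methylphenidate-sired group.

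No protein-coding gene passed the edgeR test, where the smallest adjusted p was 0.113, although 1612 genes had an unadjusted p under 0.05 (906 higher, 706 lower) against 893.7 expected from uniform p-values. The other 9 splits of the 6 libraries into 3 and 3 gave between 377 and 1323 such genes. With the cortical marker level as a covariate there were 711, with the choroid plexus level 1025 and with the Y-linked level 1630. The cortical and choroid plexus levels differ between the groups, so these counts do not separate the tissue share from the sire's treatment. In 14.8% of genes the groups did not overlap, against 10% by chance. The following values therefore did not pass. Among the ranked genes with higher values, the mucin gene Muc3a had a log2 fold change of 1.33 (SE 0.17, edgeR adjusted p = 0.113), from 3.06 ± 0.292 to 7.72 ± 1.22 CPM. Cyp26b1, which degrades retinoic acid, had 0.84 (SE 0.14), the ephrin receptor gene Ephb3 0.77 (SE 0.13) and Lsm11, a histone mRNA processing factor, 0.76 (SE 0.12). Smaller values were those of Camk2g (0.43), the prohormone convertase gene Pcsk1 (0.45), the semaphorin receptor gene Plxna1 (0.43), the adhesion gene Dscam (0.39) and Raph1 (0.46). Etl4 and Hivep3 had 0.54 and 0.48. Exons of Dscam, Etl4, Hivep3 and Plxna1 overlap those of other annotated genes, which leaves their counts uncertain.

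Among the ranked genes with lower values, the Wnt ligand gene Wnt2 had a log2 fold change of -1.06 (SE 0.14, edgeR adjusted p = 0.113), from 15.2 ± 0.304 to 7.30 ± 1.18 CPM. The Wnt receptor gene Fzd5 had -0.81 (SE 0.17), and Fndc1, a fibronectin type III domain gene, had -0.77 (SE 0.10, edgeR adjusted p = 0.113). The cytoskeletal genes Flna and Actn2 had -0.44 and -0.33, and the sodium-proton exchanger gene Slc9a5 had -0.33. Rasgrp2 had -0.36, Car11 -0.31, and the U1 small nuclear ribonucleoprotein gene Snrnp70 -0.28. Mapk4 had -0.35 and Sh2d5 -0.39. Rpl35a had -1.17 (SE 0.22, edgeR adjusted p = 0.343), and it passed without saline-sired library 3 (edgeR adjusted p = 0.0208). Summed over Rpl35a and its near-identical copies in the table, the log2 difference was -0.30 (SE 0.07, exact two-sided permutation p = 0.1), with the copies at 44.6 ± 18.1 CPM in the saline-sired and 52.0 ± 0.408 in the methylphenidate-sired group. Rpl35a shares sequence with 14 near-identical copies. Exons of Mapk4, Rasgrp2 and Fzd5 each overlap those of an annotated gene on the other strand, and Sh2d5 overlaps exons of Kif17. The counts of these genes are therefore uncertain. DESeq2 called all 24 ranked genes.

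Markers of medium spiny neurons, the projection neurons of the striatum, were lower as groups. In the shared medium spiny neuron list, all 14 members had negative fold changes (median -0.19, camera adjusted p = 9.55e-08; adjusted p = 0.493 with an estimated correlation). Among them Scn4b had -0.29 (SE 0.07) and Rgs9 -0.27 (SE 0.08). Of the indirect-pathway medium spiny neuron list 7 of 8 were negative (median -0.15, camera adjusted p = 0.00677; adjusted p = 0.493 with an estimated correlation), with Adora2a, an adenosine receptor gene, at -0.23, and Plxdc1 at 0.40. Of the direct-pathway medium spiny neuron list 7 of 8 were negative (median -0.14, camera adjusted p = 0.0112; adjusted p = 0.493 with an estimated correlation), with Tac1 at -0.32. Adjusted over the list alone, 1, 4 and 1 members passed in these lists, and 0 passed over all genes (edgeR), with 8, 4 and 2 at an unadjusted p under 0.05 and 1 in each list called by DESeq2. The indirect-pathway medium spiny neuron call was lost without saline-sired library 5 (camera adjusted p = 0.0631) and its median was -0.10 without methylphenidate-sired library 6, and the direct-pathway medium spiny neuron call without saline-sired library 4 (0.0592) or methylphenidate-sired library 6 (median -0.07, 0.108) and with the cortical marker level as a covariate (0.412). The dopamine receptor genes Drd1 and Drd2 had -0.21 (SE 0.08) and -0.19 (SE 0.07), Ppp1r1b, which encodes DARPP-32, had -0.22 (SE 0.08), and the neuropeptide genes Penk and Pdyn had -0.14 and -0.20; none passed the edgeR test. Pdyn had -0.07 without saline-sired library 3 or methylphenidate-sired library 6 and -0.33 without methylphenidate-sired library 2, and Drd1 had -0.14 without saline-sired library 5.

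Genes of the dopamine signalling list were lower as a group, with 16 of 23 negative (median -0.17, camera adjusted p = 0.000487; adjusted p = 0.493 with an estimated correlation) and 0 members past the edgeR test over all genes or adjusted over the list alone. At an unadjusted p under 0.05 there were 9, and DESeq2 called 1, Pde1b. Pde1b, a phosphodiesterase gene, had -0.26 (SE 0.06) and Th, which encodes the enzyme that limits dopamine synthesis, had -0.44 (SE 0.17). The list scores overlapped between the groups (0.04, -0.03 and 0.11 in saline-sired libraries 3, 4 and 5, and -0.001, 0.02 and -0.14 in methylphenidate-sired libraries 2, 4 and 6). Their difference was -0.08 (SE 0.06, exact two-sided permutation p = 0.4). Slc6a3, the dopamine transporter gene and a target of methylphenidate, fell below the filter, with at most 10 counts in a library.

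Markers of the cortical excitatory neuron list were higher as a group: 14 of 14 were positive (median 0.89, camera adjusted p = 6.73e-13; adjusted p = 0.493 with an estimated correlation), and 10 passed adjusted over the list alone, against 0 over all genes (edgeR; 12 at an unadjusted p under 0.05, and 2 by DESeq2). Slc17a7, the vesicular glutamate transporter gene, was at 337, 163 and 438 CPM in the saline-sired libraries and at 540, 570 and 616 in the methylphenidate-sired ones. Nptx1 had a log2 fold change of 0.69 (SE 0.15) and Neurod2 0.95 (SE 0.27). Saline-sired library 4 had the lowest score of this list (-1.24), and without it the median was 0.57. The presynaptic release machinery was higher with 19 of 21 positive (median 0.22, camera adjusted p = 1.34e-08; adjusted p = 0.493 with an estimated correlation), including Rims1 (0.37, SE 0.08) and Snap25 (0.30, SE 0.08), with 6 past the test adjusted over the list alone and 0 over all genes (edgeR; 9 at an unadjusted p under 0.05, and 5 by DESeq2). Its scores moved with those of the cortical markers, lowest in saline-sired library 4 (-0.21). With the cortical marker level as a covariate the presynaptic median was 0.03 (camera adjusted p = 0.0528).

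The immediate early genes, which neurons induce on activity, were higher as a group: 21 of 21 were positive (median 0.66, camera adjusted p = 2.41e-08; adjusted p = 0.493 with an estimated correlation), and 0 passed over all genes or adjusted over the list alone (edgeR; 7 at an unadjusted p under 0.05, and 1 by DESeq2). Arc had a log2 fold change of 1.17 (SE 0.36), Fos 1.05 (SE 0.58), Dusp6 0.76 (SE 0.19) and Egr1 0.68 (SE 0.27). Fos had 0.63 without saline-sired library 3 and 2.07 without saline-sired library 4, and Egr1 had 0.35 without methylphenidate-sired library 4. The scores overlapped between the groups, at -0.65, 0.20 and -0.42 in saline-sired libraries 3, 4 and 5 and at 0.29, 0.68 and -0.09 in methylphenidate-sired libraries 2, 4 and 6. The median was 0.35 without methylphenidate-sired library 4 and 0.44 without saline-sired library 3.

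**Figure D2:**
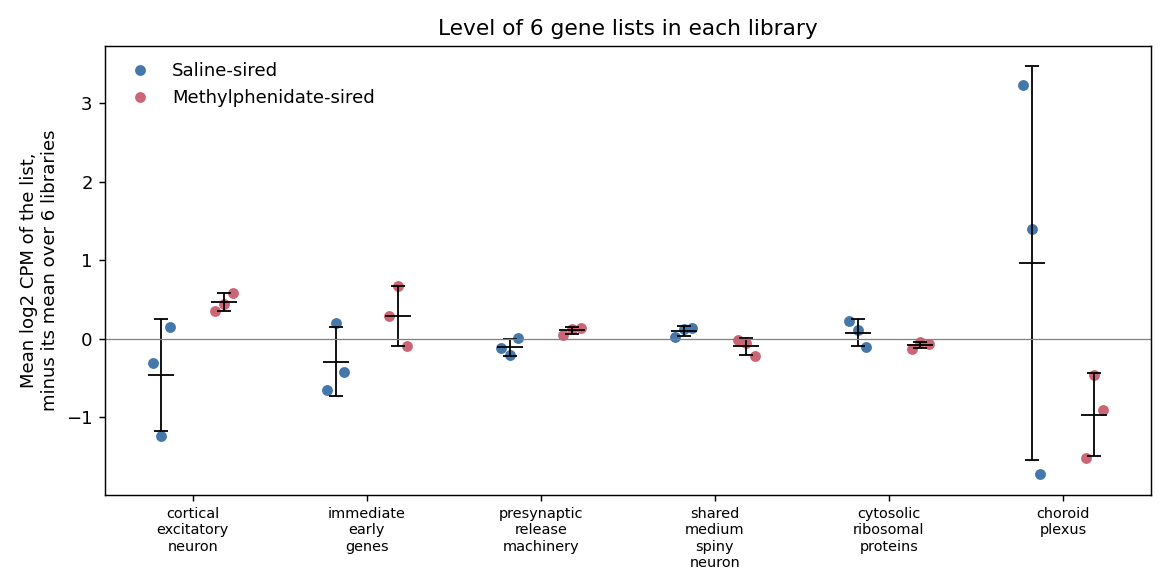
List scores (mean log2 CPM, centred over 6 libraries) of 6 gene lists, with 1 point per library and bars for the mean ± SD of 3 libraries per group. Cortical markers range from -1.24 to 0.15 in the saline-sired and from 0.36 to 0.58 in the methylphenidate-sired group, and choroid plexus markers reach 3.22 and 1.40 in saline-sired libraries 3 and 4.

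Further lists were higher. The noradrenaline and serotonin signalling list had a median of 0.24 with 11 of 19 positive (camera adjusted p = 0.0274; adjusted p = 0.493 with an estimated correlation), with the adrenoceptor gene Adra1d at 0.90 (SE 0.19) and the serotonin receptor gene Htr2a at 0.36 (SE 0.09). ADHD-associated genes had 13 of 19 positive (median 0.11, camera adjusted p = 0.0112; adjusted p = 0.493 with an estimated correlation). Their 2 members of lowest p, Dusp6 (0.76) and Snap25 (0.30), also stand in the immediate early and presynaptic lists. The mitochondrially encoded genes were positive in 13 of 13 (median 0.12, camera adjusted p = 0.000239; adjusted p = 0.641 with an estimated correlation), with ND4 and ND1 both at 0.22. Their median was 0.07 without saline-sired library 3 (camera adjusted p = 0.0495), 0.07 without methylphenidate-sired library 4 and 0.19 without saline-sired library 5. ND4 had 0.14 without saline-sired library 3, and ND1 had 0.35 without saline-sired library 5. The list of glutamate receptors and postsynaptic density had 18 of 30 positive (median 0.04, camera adjusted p = 0.0274; adjusted p = 0.641 with an estimated correlation), with Homer2 at 0.44 and Grin2a at 0.33. Adjusted over the list alone, 2, 3, 0 and 4 members passed in these lists, in the order given, and 0 over all genes (edgeR), with 5, 4, 0 and 10 at an unadjusted p under 0.05 and 1, 3, 0 and 2 called by DESeq2. The noradrenaline and serotonin signalling call was lost without saline-sired library 3 (median 0.16, camera adjusted p = 0.0972) or 4 (median 0.09, 0.0592) or methylphenidate-sired library 2 (0.118). The glutamate call was lost without the same libraries (0.163, 0.165 and 0.179), and the ADHD call without methylphenidate-sired library 4 (0.0664). Without saline-sired library 5 the medians of the ADHD-associated genes and of glutamate receptors and postsynaptic density were 0.17 and 0.09. The ADHD median was 0.07 without saline-sired library 3, and also without methylphenidate-sired library 2 or 4.

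The choroid plexus markers were lower in 13 of 13 (median -2.84, camera adjusted p = 0.000566; adjusted p = 0.641 with an estimated correlation), and 12 passed adjusted over the list alone, against 0 over all genes (edgeR; 12 at an unadjusted p under 0.05, and 0 by DESeq2, which gave an adjusted p to 7). Ttr, the transthyretin gene and the most abundant of them, was at 1905, 306 and 9.88 CPM in saline-sired libraries 3, 4 and 5, and at 14.7, 61.3 and 33.6 in methylphenidate-sired libraries 2, 4 and 6. Sostdc1 had a log2 fold change of -3.63 (SE 1.09) and Aqp1 -3.31 (SE 0.99). Without saline-sired library 3 the list's median was -1.45, with Sostdc1 at -2.02 and Aqp1 at -1.54. The cytosolic ribosomal proteins were lower in 29 of 29 (median -0.18, camera adjusted p = 7.87e-08; adjusted p = 0.641 with an estimated correlation), with Rps9 at -0.31 and Rps27 at -0.24, and their median was -0.09 without saline-sired library 3. Rps9 had -0.18 without saline-sired library 4. The ependymal markers (median -0.59, 10 of 10 negative, with Dynlrb2 at -1.11 and Foxj1 at -0.60) and the interferon-stimulated and inflammatory genes (median -0.66, 13 of 14 negative, with Gbp2 at -1.11 and Ifit3 at -0.99) each had a camera adjusted p of 0.0112 and an adjusted p = 0.641 with an estimated correlation. Their scores were highest in saline-sired library 3 (0.98 and 1.02), and without it the medians were -0.0027 and -0.14 (camera adjusted p = 0.663 and 0.627), with Foxj1 at -0.34, Gbp2 at -0.70 and Ifit3 at -0.41. The interferon call was also lost without methylphenidate-sired library 2 (camera adjusted p = 0.0508). The hypothalamic and amygdalar neuron list had 8 of 8 negative (median -0.50, camera adjusted p = 0.0105; adjusted p = 0.493 with an estimated correlation), with Pomc at -1.29. Oxt had -2.48 on counts of 13, 11 and 39 against 0, 2 and 9, with -1.55 without saline-sired library 5 and -4.20 without methylphenidate-sired library 6. The hypothalamic median was -0.82 without methylphenidate-sired library 4 and -0.28 without methylphenidate-sired library 6, and the call was lost with the cortical marker level as a covariate (camera adjusted p = 0.284). The blood markers had 5 of 5 negative (median -0.54, camera adjusted p = 0.0273; adjusted p = 0.641 with an estimated correlation), with Hbb-bs at -0.62 and Hba-a2 at -0.54. Their call was lost without saline-sired library 3 (camera adjusted p = 0.163) or 4 (0.133) or methylphenidate-sired library 6 (median -0.22, 0.456), and the blood median was -0.85 without saline-sired library 5 and -0.96 without methylphenidate-sired library 4. Hbb-bs had -0.26 without methylphenidate-sired library 6 and -0.98 without library 4, and Hba-a2 had -0.22 and -0.96. In the lists of ribosomal, ependymal, interferon, hypothalamic and blood genes 0 members passed adjusted over the list alone or over all genes (edgeR), with 6, 2, 1, 4 and 0 at an unadjusted p under 0.05. DESeq2 called 0 of them. It gave an adjusted p to 29 of 29 ribosomal members, but to 2 of 10 ependymal, 6 of 14 interferon, 3 of 8 hypothalamic and 4 of 5 blood members.

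The other 19 lists tested did not pass the set test. Median log2 fold changes of neuronal lists were -0.16 for cholinergic interneurons (Chat -0.33, Tacr1 -0.12), -0.06 for other GABAergic interneurons (Cck 0.80, Vip 0.92), -0.13 for thalamic, pallidal and septal neurons (Zic1 -0.27, Calb2 -0.38) and -0.16 for neuroblasts (Igfbpl1 -0.55, Mki67 -0.44). They were 0.02 for GABA signalling (Gabbr2 0.59, Gabra3 0.53), -0.03 for neurotrophin signalling (Gfra2 0.65, Bdnf 0.93) and -0.07 for neuropeptides. Among other cell types, medians were -0.01 for astrocytes (Gfap -0.37, Slc1a2 0.11), -0.21 for oligodendrocytes (Mog -0.25, Cnp -0.25), -0.02 for their precursors (Tnr 0.17, Pdgfra -0.12), -0.02 for microglia (C1qc -0.18, Aif1 0.45), -0.05 for endothelial and mural cells (Tagln -0.70, Acta2 -0.53) and -0.13 for meningeal fibroblasts (Dcn -0.69, Igf2 -1.37). Further medians were 0.03 for glucocorticoid-responsive genes (Mt1 -0.34, Mt2 -0.41), -0.10 for clock genes (Dbp -0.33, Rorb 0.36), 0.04 for chromatin enzymes (Uhrf1 -0.77, Kdm6b 0.33), -0.02 for imprinted genes (Gnas 0.20), -0.03 for nuclear-encoded oxidative phosphorylation genes (Cox5b -0.30, Ndufa1 -0.20) and -0.19 for heat shock genes (Hspb1 -0.64, Pdia4 -0.38). Adjusted over the list alone, 5 of 20 GABA signalling genes passed, 1 clock gene and 1 neurotrophin gene, and 0 in the other 16 lists. Median and mean differed in sign for chromatin enzymes (mean -0.03), neurotrophin signalling (0.05), neuropeptides (0.04), oligodendrocyte precursors (0.01) and other GABAergic interneurons (0.06). The test pointed with the median for chromatin enzymes (up), neuropeptides and other GABAergic interneurons (down), and with the mean for neurotrophin signalling and oligodendrocyte precursors (up). The camera adjusted p of these lists lay between 0.0773 and 0.885, and the sex-chromosome genes, with only Xist past the filter, could not be tested as a list. Leaving out 1 library gave 9 of these lists a call. Without saline-sired library 5 the camera adjusted p was 1.3e-05 for the oligodendrocyte list, 0.000641 for heat shock and unfolded protein response, 0.00318 for meningeal fibroblast, 0.00838 for oxidative phosphorylation, nuclear-encoded, and 0.0108 for endothelial and mural markers. It was 0.0315 for cholinergic interneuron and 0.0117 for circadian clock genes without saline-sired library 3, and 0.0248 for GABA signalling and 0.00366 for neuroblast and progenitor markers without saline-sired library 4. Without methylphenidate-sired library 2 the endothelial (0.00205) and meningeal (0.00687) lists passed, without library 4 the oligodendrocyte (0.0486) and oxidative phosphorylation (0.0243) lists, and without library 6 the oligodendrocyte list (0.00548).

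Single libraries moved many of the gene values in these 19 lists by more than 1.5 times. Without saline-sired library 4, which moved the most of them, Cnp had -0.0010, Mog -0.04, Gfap -0.14, Bdnf 0.51, Chat -0.19, Cck 0.48, Vip 0.58, Zic1 -0.09, Calb2 -0.17, Hspb1 -0.37 and Pdia4 -0.13. Without saline-sired library 3, Igf2 had -0.49, Igfbpl1 -0.32, Mki67 -0.24 and Slc1a2 0.04. Without saline-sired library 5, Cnp had -0.44, Mog -0.43, Slc1a2 0.18 and Tacr1 -0.08. Calb2 had -0.22, Mog -0.13 and Cnp -0.14 without methylphenidate-sired library 2. Without methylphenidate-sired library 4, Kdm6b had 0.16, Acta2 -0.29, Mt2 -0.64 and Aif1 0.67, and without library 6, Tagln had -0.41, Slc1a2 0.18 and Aif1 -0.0018.

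Of the 36 lists, 17 passed camera at a correlation of 0.01, 7 higher and 10 lower, 0 passed with an estimated correlation (smallest adjusted p = 0.493), and 0 passed fry (smallest adjusted p = 0.349). Over the other splits of the libraries, between 5 and 17 lists passed camera at 0.01. Whether the effect of the sire's treatment differed between female and male offspring, and which genes differed between the sexes, was not tested, because no label ties a column to a sex and none was assigned from expression values.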

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

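Alternatives with covariates or without saline-sired libraries 3 and 4, and the immediate early genes that stand in no other list, were chosen after seeing the data. The count of genes past the test was 4, and it was 183 with DESeq2, 473 at an unadjusted p under 0.05 and a fold of at least 1.5, 1 with at least 10 counts in every library, and 0 among protein-coding genes alone (1450 at an unadjusted p under 0.05). It was 2 with the Y-linked level, 1 with the cortical level and 2 with the choroid plexus level as a covariate, 0 without saline-sired libraries 3 and 4 (1 saline-sired library against 3, assumed to vary like the others), and between 1 (without methylphenidate-sired library 6) and 4 without each library in turn. The cause of the difference between edgeR and DESeq2 was not tested; all 183 DESeq2 calls had an edgeR p under 0.05, and DESeq2 made more calls among unchanged genes on simulated counts (43 against 10). The 4 genes past the test kept their direction in 68 of 68 comparisons with an alternative and lost their call in 26, and limma-voom also gave 4 genes, 2 of them among these. The count of lists was 17, and it was 0 with an estimated correlation, 9 with the choroid plexus level as a covariate, and between 14 and 21 without each library in turn. Of the 17, 7 also passed with the cortical level and 8 with the choroid plexus level.

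With the cortical level as a covariate the direction of the set test turned for blood markers (median 0.00084) and glutamate receptors and postsynaptic density (-0.0218). With the choroid plexus level it turned for interferon genes (0.015). Without saline-sired libraries 3 and 4, which sets 1 saline-sired library against 3 and decides no direction for the group, it turned for choroid plexus markers (0.82), cytosolic ribosomal proteins (0.028), glutamate receptors and postsynaptic density (-0.0219) and interferon genes (0.12). The cause was not tested. Leaving out each library turned the direction of the test for results that had not passed, over these ranges of the fold change or list median (log2): Aif1 -0.0018 to 0.67, Xist -0.71 to 0.47, astrocyte -0.082 to 0.077, chromatin and DNA methylation enzymes -0.0060 to 0.070, glucocorticoid-responsive genes -0.033 to 0.14, heat shock and unfolded protein response -0.31 to 0.016, imprinted genes -0.053 to 0.021, microglia -0.12 to 0.020, neuroblast and progenitor -0.28 to -0.051, neuropeptides -0.15 to 0.076, oligodendrocyte -0.37 to 0.084, oligodendrocyte precursor -0.13 to 0.043, other GABAergic interneuron -0.074 to -0.0046, oxidative phosphorylation, nuclear-encoded -0.051 to 0.013 and thalamic, pallidal and septal neuron -0.25 to 0.091. No paired analysis was possible because the numbers of the columns, as a set, are not the labels' replicate numbers. The replicate block was not run for the same reason. The sex covariate, the females-only fit and the sex tests were not run, because no label ties a column to a sex and none was assigned from expression values. Planned tests on the other 12 columns (FPKM and TPM) were tried and left out after their results had been seen, since those columns name only a group. The immediate early genes in no other list (20 genes) had a median of 0.65 (camera adjusted p = 1.07e-07). Slc6a3, with at most 10 counts in a library, had a log2 fold change of -0.36 (SE 1.27, edgeR adjusted p = 0.965) with no filter. On counts of this gene this low, such an error leaves differences of several fold undetectable.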

Other observations

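The tests in this part were chosen after the results were seen, except the DESeq2 fit, the fit without saline-sired library 4 and the counts over other splits of the libraries; using that fit to weigh an explanation was also chosen afterwards. DESeq2 called 183 of 12838 genes to which it gave an adjusted p. Of 21 presynaptic release genes it called 5 and of 20 GABA signalling genes 3, all higher, and of the ADHD-associated genes 3, all higher. The ADHD-associated calls were Dusp6, Snap25 and Mef2c. Of these, Dusp6 is also the immediate early gene it called, and Snap25 is among the 5 presynaptic calls. It called Pde1b, Scn4b, Adora2a and Tac1 lower, 1 each in the dopamine and the shared, indirect-pathway and direct-pathway medium spiny neuron lists. These genes had edgeR p-values under 0.05 and did not pass its adjusted threshold.

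The lower counts of 3 Rpl30 pseudogenes may reflect how reads were divided among near-identical copies. Summed over Rpl30 and the 10 copies counted in the table, the family was at 84.1 ± 11.1 CPM in the saline-sired and 78.3 ± 3.24 in the methylphenidate-sired group, a log2 difference of -0.10 (SE 0.12, exact two-sided permutation p = 0.5; the smallest p that 3 against 3 allow is 0.1). Acaca and Gm5182 together were higher by 0.24 (SE 0.04, exact two-sided permutation p = 0.1), more than moved reads alone would give, and this leaves the same explanation open for Gm5182. Within the saline-sired group the SD was 8.0 CPM for Acaca, 7.83 for Gm5182 and 0.643 for their sum, so their counts moved in opposite directions. For Rpl30 it was 7.96, for its copies 3.12 and for their sum 11.1, so these rose and fell together. With 3 libraries this decides neither case. Alleles that differ between families of outbred mice, which would change where reads align, and an effect of the sire's treatment were not tested and stay open. The real split gave 4 genes past the test and 1612 at an unadjusted p under 0.05. The highest of the other splits were 4 and 1323. As many past the test came from 2 of the 10 splits of the 6 libraries. The other of these set saline-sired library 3 and methylphenidate-sired libraries 2 and 6 against the remaining libraries. It put both libraries with high Y-linked transcripts on the same side, while the real split has them on opposite sides. Each of the other splits also keeps 2 libraries of a group together. A share under 0.05 cannot be reached with 10 splits, so these counts decide nothing.

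Higher cortical markers with lower medium spiny neuron markers could come from a larger share of cortex in the dissected piece. Saline-sired library 4 alone did not account for the cortical difference, whose median was 0.57 without it. Over the 6 libraries the cortical and shared medium spiny neuron levels had Pearson r = -0.65 (exact permutation p = 0.163) and Spearman rho = -0.83 (exact permutation p = 0.0583), and 1 relation was computed. These values pool both groups, between which the lists had been seen to differ in opposite directions, so they are mixed with the group difference. Without the 2 libraries farthest from the cortical median, saline-sired libraries 3 and 4, r was -0.99. There 1 saline-sired library against 3 others remained, so this value is also mixed with the group difference and decides nothing. The presynaptic score difference of 0.22 (SE 0.07) was 0.074 (SE 0.04) with the cortical level as a covariate, and since that level moves with the group, the tissue share and the sire's treatment cannot be told apart for this list. With the same covariate the shared medium spiny neuron difference was -0.16 (SE 0.13), too wide to decide, and dissection and treatment stay open; all 14 cortical markers passed the expression filter in these striatal libraries, and Rorb is also in the clock list.

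Higher immediate early genes are a hypothesis of altered activity in offspring of treated sires, against which a larger share of cortex was weighed. The score difference was 0.58 (SE 0.34, exact two-sided permutation p = 0.2), and with the cortical level as a covariate it was 1.09 (SE 0.43), so this test did not lower it, but its error is too wide to exclude the tissue share. Handling before death could also raise these genes and was not tested. For the set tests, the real split gave 17 lists, and the other splits gave between 5 and 17. With the real split included, 4 of 10 splits gave as many as 17. The number of lists past camera therefore did not set the real grouping apart from other groupings of the same libraries. Small camera p-values alone do not show an effect of the sire's treatment. A share under 0.05 could not be reached with 10 splits, so the share seen decides nothing on the sire's treatment. The other splits with 17 lists were also uneven. Some kept saline-sired libraries 3 and 4 together, as the real split does. Another put both libraries with high Y-linked transcripts on the same side.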
